A study of Brassica napus with 6 samples.

How the data were processed

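RNA-seq libraries of rapeseed (Brassica napus) silique walls were compared, 3 from a pool of long-silique accessions and 3 from a pool of short-silique accessions. Groups and replicate numbers were taken from the sample labels. Per the series design text, equal amounts of tissue were mixed into the pools, libraries were made with an Illumina kit, filtered reads were mapped to the Darmor reference genome, and uniquely mapped reads were used for quantification. The aligner and the release of the reference are not given in the sources used here. DESeq2 and edgeR are named in the submitters' processing notes, without versions.

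The authors deposited 1 table with read counts, FPKM, log2 fold changes, p-values and FDR per gene, together with positions and descriptions, per the file headers. The deposited counts are whole numbers per gene and library. The deposited FPKM are counts scaled by the authors to gene length and library total. The log2 fold change and the p-value columns are the authors' own comparison of the pools. The table holds 3248 genes with values and 59362 blank rows, which were left out. Every listed gene has an FDR of at most 0.0499 and an absolute log2 fold change of at least 1.00, and 211 have a p above the limit of 0.005 named in the series design text.

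Because the table holds only called genes, the sum of its counts is not the depth of a library. Library totals were therefore recovered by dividing counts by FPKM and genomic span, over genes with at least 200 counts and an FPKM of at least 5. This ratio equals the library total for a gene without introns and is lower for a spliced gene. The total was taken as the median of the genes within 0.5% of the 95th percentile, where they pile up, and is an estimate. The totals lay between 22892442 and 30259269 reads, so that a floor of 3 counts in 1 library corresponds to between 0.0990 and 0.131 CPM. Over 100 genes with more than 200 counts in every library, the authors' deposited log2 fold change minus that computed from these totals had a median of -0.00031. The number of genes the authors tested, 65264, was recovered from the FDR and p of the first 20 ranks.

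Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust), after filterByExpr, which left 2574 genes. The recovered totals served as library sizes without TMM factors. This departs from the planned TMM scaling, was chosen after seeing the data, and was made because TMM assumes mostly unchanged genes. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05, computed over 65264 genes, and a p of at most 0.005. Adjusting over that number treats genes outside the table as larger in p than every listed gene. Each adjusted p is therefore an upper bound for the p-values as fitted. The spread was estimated from genes selected for differing between these libraries, which may make the p-values themselves too small. Standard errors were taken from the log2 fold change and the F statistic.

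Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for named genes were fixed. List members were found by Arabidopsis locus, symbol or description in the table. The RefSeq gene table matched 0 of the gene IDs, so names come from the deposited table. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry. The named genes are the 10 higher and 10 lower called genes with the largest fitted fold, a mean of at least 1 CPM, no overlap between pools and a name; up to 2 higher and 2 lower called members of each list with the smallest p; and the tested copies of CYP78A9, CYP78A5, CYP78A6, ARF18, UPL3 and DA1.

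The planned tests of called against tested genes per subgenome and chromosome could not be run, because genes without a call were not analysed here. Higher was compared with lower instead, by two-sided Fisher's exact tests, and neighbouring called genes were compared in direction with 10000 shuffles. Genes on unplaced and random scaffolds were left out of these tests. Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, a replicate block, other thresholds and leaving out each library. Added after seeing the data were tests without the first 6 Mb of C02, tests on the authors' directions, and windows of 2 Mb. Tables and figures were made with Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

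The fits were tested on simulated data with the 2574 genes, in which 100 genes each were changed by a log2 fold of 1 and 2. For the comparison of long with short, edgeR with adjustment over 65264 genes recovered 8% of the smaller and 64% of the larger changes and called 0 unchanged genes. With adjustment over the simulated genes it recovered 35% and 93% and called 2 unchanged genes. Most simulated genes were left unchanged, whereas every listed gene was selected by the authors for differing. The recovered shares and the false calls therefore do not measure the sensitivity or the error of the calls on the data. As a check for a library deposited more than once, counts were compared within each pool. The chi-square per gene was between 3.96 and 6.63, above sampling noise in every pair, so no pair was merged; this does not tell biological from technical replicates. Strand-specific counting is not stated, so reads of overlapping antisense genes cannot be told apart, and homoeologous A and C copies may share reads.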

Results

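RNA from silique walls, the outer tissue of the rapeseed pod, was sequenced 15 days after flowering from 2 pools of accessions. One pool mixed material of 12 long-silique accessions and the other that of 11 short-silique accessions. Each pool was represented by 3 libraries. The table used here lists 3248 genes that the authors called different between the pools, so genes without a call were not analysed here. Library totals recovered from the counts and FPKM were 25731495, 30259269 and 22892442 for the long libraries and 25483275, 29256555 and 27110634 for the short libraries. The listed genes held between 0.897% and 1.19% of these totals. Nothing in the labels says that the libraries of a pool came from separate plants, so p-values measure only the spread between libraries, which may be technical.

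The comparison of the pools asked which genes of the silique wall differ between long and short siliques. Among the genes with a name in the table, the smallest p was that of BnaA09g55530D, a copy of the cytochrome P450 gene CYP78A9, known to promote seed and fruit growth (A09_random, 3280990 to 3282883). It stood at 108 ± 6.09 CPM (counts scaled to the library total; SD, n = 3) in the long pool and 4.76 ± 1.10 CPM (SD, n = 3) in the short pool. Its log2 fold change, long over short, was 4.51 with a standard error of 0.20 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.58e-09). In the opposite direction, all 12 listed senescence genes were lower in the long pool. So were 66 of the 75 listed genes of the 4 cell wall lists, against 65.6% of all listed genes. These lists hold several copies of a locus, such as NAP, ORE1 and SAG12, and copies mostly moved together, so members are not independent. No list differed from the other listed genes with edgeR and camera (smallest adjusted p = 0.207). The senescence list did with the DESeq2 Wald test at the preset correlation (adjusted p = 0.0165), but not in camera with an estimated correlation (adjusted p = 0.754). With TMM over the listed genes the called genes of the wall lists were 8 higher and 6 lower. TMM assumes mostly unchanged genes, which a table of selected genes does not hold. Both listed NAP genes with the smallest p, which encode a NAC transcription factor of leaf senescence, had log2 fold changes of -2.85 ± 0.22 (SE) for BnaC06g30680D and -2.61 ± 0.23 (SE) for BnaA07g28000D.

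In the authors' deposited table, 1116 genes were higher and 2132 lower in the long pool. Of the 2574 genes tested here, 1713 passed the thresholds (edgeR quasi-likelihood test, adjusted over the 65264 genes that the authors' p-values and FDR imply), 594 higher and 1119 lower. All 2574 fitted directions equalled those of the authors' deposited table. The split depends on the scaling: with TMM over the listed genes alone, which moved the log2 fold changes up by a median of 0.77 (range 0.31 to 0.81), 916 genes were higher and 331 lower. With DESeq2 size factors over the listed genes the counts were 915 and 278. Leaving out long silique replicate 1 or 2 reduced the 1713 calls to 1109 and 1116. The listed genes were selected by the authors for differing between these same libraries, so a second test on them is not independent evidence.

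The table lists 2 other copies of CYP78A9, both with a negative log2 fold change. BnaA04g00510D (A04, 386326 to 388352) had a log2 fold change of -1.68 ± 0.47 (SE) and BnaC08g31760D (C08, 30989298 to 30991058) one of -1.80 ± 0.47 (SE). Neither passed the test (edgeR adjusted p = 0.0883 and 0.0543), and the 2 copies stood at 0.810 and 0.674 CPM in the short pool. BnaA10g00660D, described as the related CYP78A6, was lower in the long pool, with a log2 fold change of -1.89 ± 0.44 (SE; edgeR adjusted p = 0.0256). It was given the Arabidopsis locus AT1G01190 and matched the list by description only, so it need not be a copy of CYP78A6. BnaC02g07600D, which encodes a protein related to the growth regulator DA1, was higher by 1.21 ± 0.29 (SE) on the log2 scale (edgeR adjusted p = 0.0256). It lies in the first 6 Mb of C02, where 140 of 157 listed genes were higher. The calls of BnaA10g00660D and BnaC02g07600D each ended in 5 of the 6 fits that left out 1 library. In those fits the log2 fold changes were -1.59 to -1.93 for BnaA10g00660D and 1.17 to 1.25 for BnaC02g07600D. The call of BnaA10g00660D also ended with TMM over the listed genes (log2 fold change of -1.12).

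**Figure D1:**
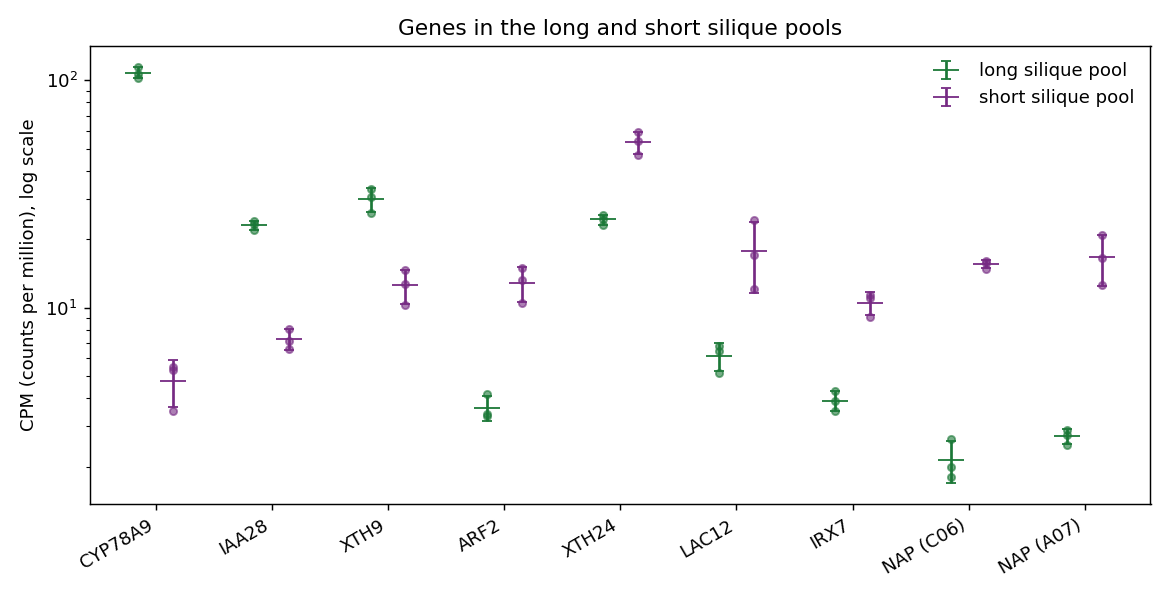
CPM on a log axis for 9 genes, with each library as a point, the mean as a horizontal mark and the SD (n = 3) as a bar, green for the long and purple for the short pool. CYP78A9, IAA28 and XTH9 lie higher in every long library than in any short library, and ARF2, XTH24, LAC12, IRX7 and both NAP genes lie lower.

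The gene groups asked which processes differ between the walls of the pools. Of the 12 senescence genes in the table, 0 were higher and 12 lower in the long pool, and 7 of these were called (9 adjusted over the list alone). Of the 25 cell wall loosening genes, 3 were higher and 22 lower, with 3 and 15 called (22 adjusted over the list alone). Of the 22 pectin modification genes, 3 were higher and 19 lower, with 2 and 11 called (21 adjusted over the list alone). All 7 secondary cell wall genes were lower, with 6 called, and of the 21 lignin genes 3 were higher and 18 lower, with 1 and 13 called (7 and 20 adjusted over the list alone). The genes tested were 11, 22, 21, 7 and 20 for these lists, in this order. Of all 2574 tested genes, 1713 were called and 2562 passed when adjusted over the tested genes alone. Passing an adjustment over a list alone therefore follows from the authors' selection, for these and the other lists.

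None of the 18 lists with at least 5 tested members stood apart from the other listed genes in the camera test (limma, smallest adjusted p = 0.207). At an unadjusted camera p under 0.05 there were 2 lists, senescence and glucosinolate. With an estimated correlation there were 0 such lists (camera, adjusted p = 0.754 for senescence). Fry, which asks only whether a list's genes move on balance one way, passed 16 of the 18 lists, on genes already selected for moving. In the fits with TMM over the listed genes, the called members of the loosening list were 3 higher and 3 lower, those of the pectin list 3 and 3, those of the lignin list 2 and 0, those of the secondary wall list 0 and 0, and those of the senescence list 0 and 5.

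**Figure D2:**
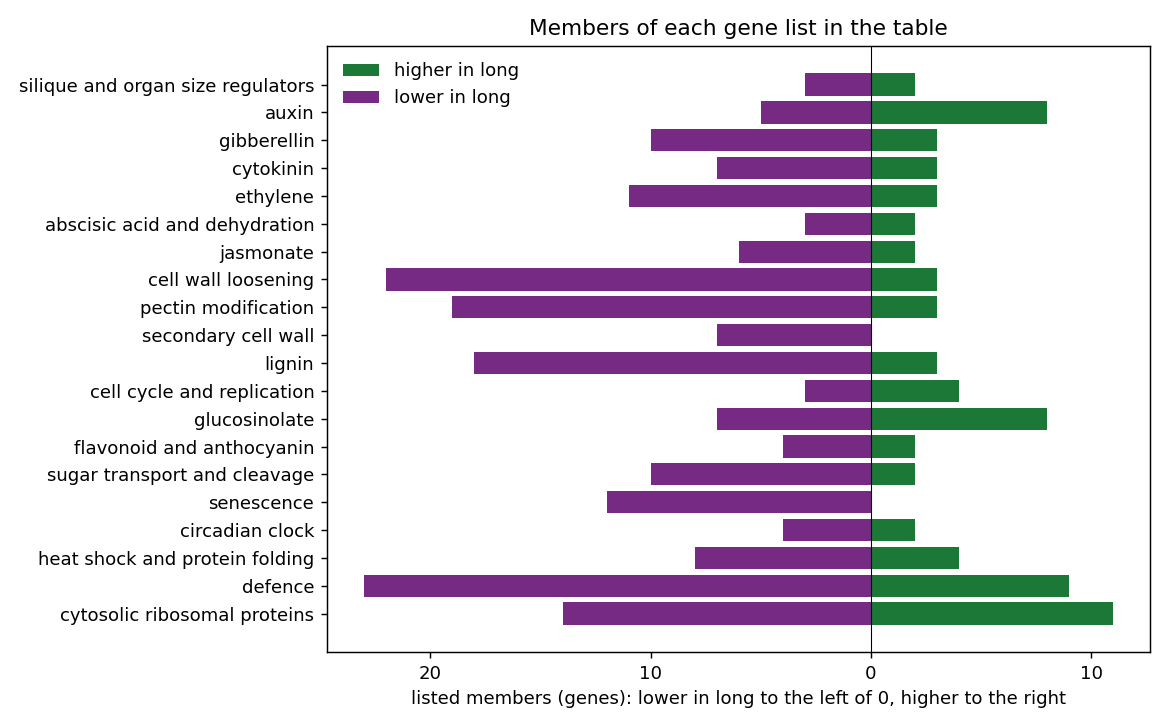
Number of genes in the authors' table for each list with at least 5 members there, with genes higher in the long pool to the right of 0 in green and genes lower to the left in purple. The senescence list has 12 lower members and 0 higher, and the loosening list has 22 lower and 3 higher.

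Among the wall genes, BnaC07g42500D, which encodes the xyloglucan-modifying enzyme XTH24, went from 53.4 ± 6.09 CPM (SD, n = 3) in the short to 24.4 ± 1.24 CPM (SD, n = 3) in the long pool. BnaA01g06750D, described as XTH22 but given the same Arabidopsis locus as BnaC07g42500D (AT4G30270), had a log2 fold change of -1.84 ± 0.22 (SE). Of the called loosening genes higher in the long pool, BnaA03g25760D (XTH9) had a log2 fold change of 1.26 ± 0.19 (SE) and BnaC02g20750D (endoglucanase 9) one of 1.98 ± 0.36 (SE). BnaA07g02370D, an exopolygalacturonase that cuts pectin, had 3 counts in the long pool and 674 in the short pool, a ratio of 217 (95% exact counting interval 73.8 to 1053). The pectinesterase gene BnaA09g55410D had a log2 fold change of -2.56 ± 0.24 (SE). Both IRX7 genes, which act in the synthesis of xylan, were lower, by -1.43 ± 0.21 (SE) for BnaA04g16260D and -1.26 ± 0.20 (SE) for BnaC04g39510D on the log2 scale. The lignin genes BnaA10g25010D (laccase-12) and BnaA06g37870D (described as cinnamoyl-CoA reductase 1) had log2 fold changes of -1.53 ± 0.24 and -1.27 ± 0.18 (SE). BnaA01g00140D, a cinnamyl alcohol dehydrogenase, was higher, by 1.38 ± 0.23 (SE). With TMM over the listed genes the calls of XTH24, both IRX7 genes, laccase-12 and BnaA06g37870D ended.

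Hormone genes went both ways. Of 13 auxin genes, 8 were higher and 5 lower, with 5 and 4 called (13 adjusted over the list alone). The auxin repressor gene IAA28 (BnaA06g27950D) had a log2 fold change of 1.67 ± 0.18 (SE) and the auxin synthesis gene YUC6 (BnaC02g48550D) one of 1.28 ± 0.19 (SE). ARF2 (BnaA05g14370D), a repressor of auxin responses, had a log2 fold change of -1.82 ± 0.22 (SE). Of 13 gibberellin genes, 3 were higher and 10 lower, with 3 and 7 called (12 adjusted over the list alone). GA2OX1 (BnaC03g21150D), which inactivates gibberellin, had 53 counts in the long pool and 0 in the short pool, at least 18.3-fold higher against a floor of 3 counts over the short pool. The receptor gene GID1B (BnaA09g55590D) and the synthesis gene GA20OX3 (BnaC09g48370D) had log2 fold changes of -2.64 ± 0.34 and -2.45 ± 0.35 (SE). GID1B lies near the CYP78A9 copy BnaA09g55530D on A09_random (3324916 to 3326756). Random scaffolds were left out of the position tests, and closeness on them need not be closeness on the chromosome. Of 14 ethylene genes, 3 were higher and 11 lower, with 0 and 7 called. Of these 14 genes, 12 are described as homologs of ACC oxidase, related dioxygenases not known to make ethylene, and 2 as ACC oxidase itself. Cytokinin genes were 3 higher and 7 lower, with 1 and 3 called, and jasmonate genes 2 and 6, with 0 and 3 called. With TMM over the listed genes the calls, higher and lower, were 8 and 2 for auxin, 3 and 2 for gibberellin, 1 and 1 for ethylene, 2 and 0 for cytokinin and 2 and 1 for jasmonate.

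Genes with day-length and clock roles were also listed. PRR7 (BnaC02g03470D) and REVEILLE 1 (BnaC02g07210D), both in the first 6 Mb of C02, had log2 fold changes of 1.47 ± 0.21 and 1.56 ± 0.30 (SE). A pair of PRR5 copies, BnaA06g26980D and BnaA02g32550D, had log2 fold changes of -1.65 ± 0.19 and -1.70 ± 0.29 (SE). FLC (BnaC09g46540D), a repressor of flowering, had a log2 fold change of -2.50 ± 0.35 (SE), and FT (BnaC02g45250D), a promoter of flowering, one of -1.31 ± 0.21 (SE). CO (BnaA10g18430D) and SOC1 (BnaA04g26320D) were higher, by 1.52 ± 0.36 and 1.09 ± 0.26 (SE; edgeR adjusted p = 0.0278 and 0.0306) on the log2 scale. Their calls ended in 4 and 5 of the 6 fits that left out 1 library. The call of REVEILLE 1 ended without long silique replicate 1 (log2 fold change of 1.25), and those of BnaA02g32550D and FT ended with TMM over the listed genes. With DESeq2 size factors that of BnaA06g26980D ended too (log2 fold change of -0.71). The flowering list as a whole had 2 higher and 2 lower members, and the clock list 2 and 4.

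The remaining lists held 9 higher and 23 lower defence genes, 11 and 14 genes of the cytosolic ribosomal protein list, 1 of which (BnaC03g74040D) is described as mitochondrial, 8 and 7 glucosinolate genes, 2 and 10 sugar transport and cleavage genes, 4 and 8 heat shock genes and 4 and 3 cell cycle genes. Shorter lists held 2 higher and 4 lower flavonoid genes, 2 and 3 abscisic acid genes, 2 and 0 brassinosteroid genes, 1 and 1 photosynthesis genes and 0 and 2 wax and cutin genes. Of the heat shock list, 4 members encode HSPRO2, a nematode resistance protein that is not a heat shock protein. They include both called genes with the smallest p among those lower. The marker lists of other tissues held 1 seed gene and 4 petal, stamen and pollen genes. The seed gene, the storage protein BnaA09g50780D, had 3 counts in the long pool and 270 in the short pool, a ratio of 86.7 (95% exact counting interval 29.4 to 423). No gene of the fruit patterning list was in the table.

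The largest fitted changes included genes with no reads in 1 pool. BnaC05g29670D, which encodes the chloroplast protein ELIP1, had 0 counts in the long pool and 1030 in the short pool, at least 331-fold lower against a floor of 3 counts over the long pool. BnaC06g11640D, described as Sin3-like 6, had 231 counts in the long and 0 in the short pool, at least 79.9-fold higher. Nucleolin 1 (BnaA07g32570D) was at 25.3 ± 5.62 CPM (SD, n = 3) in the long and 0.951 ± 0.242 CPM (SD, n = 3) in the short pool. Using at least 10 counts in every library of 1 pool and at most 3 counts in total over the other, 30 genes were detected in the long pool only and 129 in the short pool only. Leaving out a library loosens this rule, so both counts can only rise. The first count rose to 54 without short silique replicate 3 and to 49 without long silique replicate 3 or short silique replicate 2. The second rose to between 159 and 170. Reads of near-identical copies could be shared between genes, and intervals and floors cover counting error only.

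The positions of the called genes asked whether linked genes changed together, as pools of different accessions allow. On C02, 124 of 170 called genes were higher in the long pool (72.9%; Fisher's exact test against the other chromosomes, two-sided, adjusted p = 5.28e-24 over 19 chromosomes). Of these, 106 lay in the first 6 Mb, where 140 of 157 listed genes were higher. Fisher's exact tests of positions, here and for the subgenomes, count each gene as independent. Neighbouring called genes shared a direction more often than in shuffles, so these p-values may be too small. The share of higher genes was below that of the other chromosomes on C06 (9 of 67, adjusted p = 0.000358), A02 (14 of 74, adjusted p = 0.00714) and C01 (5 of 36, adjusted p = 0.0205), by Fisher's exact test. The other chromosomes include C02, whose higher genes raise the share compared with. Without the genes of the first 6 Mb of C02, added later, 2 chromosomes passed, so C06, A02 and C01 did not all do so. Without short silique replicate 3 only 1 chromosome passed. Of 86 windows of 2 Mb, an alternative chosen after seeing the data, 9 passed on the authors' directions (Fisher's exact test, adjusted p of at most 0.05). Those off C02 were A07 from 22 to 24 Mb (18 higher, 5 lower), A03 from 0 to 2 Mb (13 and 3) and from 24 to 26 Mb (11 and 2), C09 from 2 to 4 Mb (9 and 2) and from 14 to 16 Mb (11 and 3), and C06 from 34 to 36 Mb (1 and 26).

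**Figure D3:**
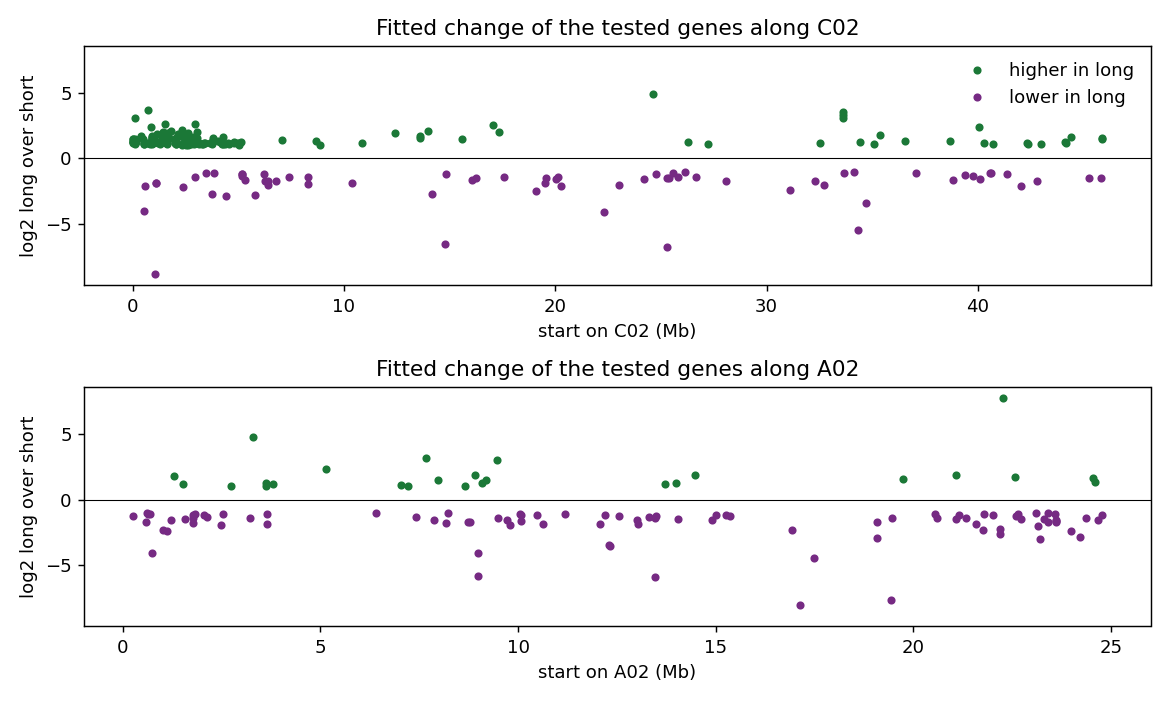
Fitted log2 fold change, long over short, of the tested genes against their start on C02 (top) and A02 (bottom) in Mb, with green points higher and purple points lower in the long pool. The first 6 Mb of C02 holds 140 of the genes listed as higher and 17 listed as lower.

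Called genes of the A subgenome were higher in 211 of 640 cases and those of the C subgenome in 285 of 726 (odds ratio 0.76, two-sided Fisher's exact p = 0.0179). Without the genes of the first 6 Mb of C02, an alternative chosen after seeing the data, the odds ratio was 1.18 (Fisher's exact p = 0.199). It was 1.04 with TMM and 1.07 with DESeq2 size factors over the listed genes, and the difference also missed p = 0.05 without long silique replicate 1 (Fisher's exact p = 0.118), with no filter (p = 0.0703) and over the authors' directions of all listed genes (p = 0.322). Neighbouring called genes shared their direction in 67.6% of 1347 pairs, against a mean of 58.4% in 10000 shuffles within chromosomes (permutation p = 0.0001, the smallest they can give). Without the first 6 Mb of C02 the share was 65.3% against 57.9%.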

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

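The scaling, taken from the recovered totals after seeing the data, decides the split of higher and lower genes. Against 594 higher and 1119 lower, TMM over the listed genes called 916 and 331, DESeq2 size factors 915 and 278, and column sums of the listed genes 850 and 680; a table of selected genes has no unchanged majority to centre on. An adjusted p of at most 0.01 called 1112 genes, 365 of them higher. Leaving out 1 library called 1109 to 1434 genes, 364 to 495 higher and 736 to 952 lower, with fewer samples. The replicate block called 1228 genes. Same-numbered libraries had correlations of deviations of 0.01, 0.01 and -0.02, so the numbers share only a name.

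No list passed camera in the main setting or with any library left out, against 16 lists with fry, 18 with its mixed test, added later, and 1 (senescence, adjusted p = 0.0165) with the DESeq2 Wald test at the preset correlation; the cause was not tested. Camera with an estimated correlation passed 0 lists (senescence, adjusted p = 0.754). List directions turned in 11 of 300 cases, none past the threshold: ribosomal proteins with fry (adjusted p = 0.76); the clock list with TMM (0.982), size factors (0.934), no filter (0.989), the CPM filter (0.913) and without long silique replicate 2 (0.934) or 3 (0.936); heat shock with TMM (0.986), size factors (0.96) and without long silique replicate 1 (0.973); and defence without long silique replicate 1 (0.973). Over all 6 left-out fits, turned or not, these p were 0.911 to 0.973 for the clock list and 0.876 to 0.973 for heat shock and for defence.

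The odds ratio of the A over the C subgenome was 1.04 with TMM, 1.07 with size factors, 0.82 with no filter (no longer past the threshold), 0.70 to 0.79 with left-out libraries (past it in all but 1) and, added later, 0.92 over the listed genes (not past it) and 1.18 without the first 6 Mb of C02, whose genes are mostly higher. The 4 chromosomes past the threshold became 2 with TMM, 1 to 6 with left-out libraries and, added later, 8 over the listed genes and 2 without the C02 segment. Genes detected in 1 pool only became 11 and 72 with at least 20 counts, 14 and 63 with 0 counts in the other pool, and 35 to 54 and 159 to 170 with left-out libraries. The stricter rules can only lower these counts, and leaving out a library can only raise them. Over the 91 named genes and all alternatives, 156 of the 1540 fits lost a call and 0 turned direction; 67 of the 89 calls held with TMM and 64 with size factors. A mean under 1 CPM was found for 49.5% of the listed genes, which limits their precision.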

Other observations

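All tests in this part were chosen after the results were seen, except those of genes detected in 1 pool only. Copies of a gene on both subgenomes mostly moved together. Of 145 Arabidopsis loci with exactly 1 listed A gene and 1 listed C gene, both copies were higher for 18, both lower for 112, and opposite for 15. The shared direction in 89.7% of pairs compares with 70.9% if A and C genes were independent (Fisher's exact p = 4.29e-12). The homeobox gene ATHB-12 (BnaA09g55520D), chosen after its values were seen, lies beside the CYP78A9 copy on A09_random (3265214 to 3266469). It went the other way, with a log2 fold change of -4.55 ± 0.35 (SE). GID1B (BnaA09g55590D) and the pectinesterase gene BnaA09g55410D lie near the same copy by their coordinates and were also lower. A09_random is a random scaffold, so closeness there need not be closeness on the chromosome. Linkage of these genes was not tested.

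Genes of the first 6 Mb of C02 were mostly higher in the long pool, 140 against 17. If every accession of the short pool lacked these genes or their reads, most would have at most 3 counts there. Only 2.86% of the higher genes did, against 11.89% elsewhere (Fisher's exact p = 0.000409). Absence from part of the 11 accessions of the short pool would leave counts and was not tested. The log2 folds of the block had an interquartile range of 0.37, against 0.54 for higher genes elsewhere matched on CPM (permutation p = 0.0029). The median of the block, 1.19 against 1.27 (permutation p = 0.0012), lay nearer the authors' limit of 1. A cut at that limit may narrow the range, which was not tested. A copy-number difference of the whole segment therefore stays undecided. Of the listed A copies of the block's loci, 63.6% (7 of 11) were lower, against 33.3% (10 of 30) for other higher C genes (Fisher's exact p = 0.151). Among all 1205 listed genes on A chromosomes, 789 were lower. The copies are too few to decide whether the segment replaced its A copy in part of the long pool. A linked regulator and partial loss of reads to sequence variants were not tested.

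Of the listed senescence and wall genes, 78 of 87 were lower in the long pool, against 65.6% of all listed genes. Several share an Arabidopsis locus with another member, so they are not independent. No such list passed camera (smallest adjusted p = 0.207), and with TMM the called wall genes were 8 higher and 6 lower. A single linked segment would hold most of the 78 lower genes, but at most 3 of them lay in 1 window of 2 Mb. An earlier stage of the long walls on the day of sampling may also lower them, and would be expected to raise cell cycle genes. That list had 4 higher and 3 lower members (Fisher's exact p = 0.24), too few to decide; 2 of the 4 lie in the C02 segment, and without it the p was 0.654. Stage cannot be told apart from silique length with 1 day sampled.

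Of the genes detected in 1 pool only, 27.8% (5 of 18 with another listed copy) had a copy that moved the other way, against 14.8% of other listed genes (Fisher's exact p = 0.172), so a move of reads between copies stays open. An Arabidopsis locus was given for 32.7% of the 159 genes, against 66.7% of the other listed genes (Fisher's exact p = 1.88e-17). A lower share was predicted if less conserved genes were present or absent in the accessions. A gene without a given locus need not be less conserved: BnaAnng22100D, described as a tubulin alpha chain, has none. The genes were not matched on expression either, so the test cannot decide this.

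Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real split, the real one itself, with 1713 genes against at most 0 in the others. With 10 splits no share under 0.05 is possible, and the listed genes were selected on the real split.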
